A study of Mus musculus with 8 samples.

How the data were processed

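RNA was sequenced from 8 mouse libraries, 2 from each of 4 groups: splenic B-1a cells and splenic follicular B cells, each from control mice that carried Cd19-Cre alone and from mice in which both copies of Cic were flanked by loxP sites and Cd19-Cre was present. The mice were 12 weeks old, per the labels. Cells were sorted from the spleen as IgM+ CD19+ CD5+ CD43+ (B-1a) or B220+ CD93- CD23+ CD21 low-to-mid (follicular B), per the labels' protocols. A SMART-seq v4 kit was used for all B-1a libraries and a TruSeq RNA v2 kit for all follicular B libraries, per the labels' protocols, so kit and cell type are the same split and expression levels were not compared between the cell types. Whether the libraries of a group came from separate mice is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical.

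The deposited values were in 2 tables, 1 for each cell type. Reads were aligned and assembled with HISAT2 and StringTie against mm10 (GRCm38), per the submitters' processing notes; versions and the strand setting are not given in the sources used here. Each table lists only genes the authors had already selected: 712 in B-1a cells and 358 in follicular B cells, all with a signed fold change of at least 1.2 in size and a raw p-value under 0.05 (smallest sizes 1.20, largest p-values 0.0498 and 0.0499). The authors' deposited fold change is signed (negative where the Cic-deficient mean is lower), and it lay between 0.973 and 1.08 times (B-1a) or 0.971 and 1.02 times (follicular B) the ratio of geometric means of FPKM + 1, so that it understates the change of low genes. The authors' deposited p-value is unadjusted, and the test behind it is not given in the sources used here. The deposited FPKM values and whole read counts per library were used for the genes that were higher in Cic-deficient cells (325 and 180 genes); for the genes that were lower, the authors' fold change and p-value are all that was used here. Cic itself is in neither table. All gene identifiers matched the RefSeq annotation of GRCm38.p6 (712 of 712 and 358 of 358), from which coordinates were taken (1-based).

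Library sizes were recovered from the deposited counts and FPKM values. Within a table, the ratio of count to FPKM differs between libraries by the same factor for nearly all genes, and with the transcript length it gives the total behind FPKM. The estimates were 48.4 and 47.9 M reads for the Cic-deficient B-1a libraries, 52.3 and 53.4 M for the control B-1a libraries, 48.9 and 48.8 M for the Cic-deficient follicular B libraries and 40.8 and 52.3 M for the control follicular B libraries. The relative sizes are medians over genes with at least 100 reads, and the absolute size is a median over genes with at least 200 reads and 1 RefSeq transcript of known GENCODE M21 length. These totals are estimates, and intervals and lower bounds cover counting error only.

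The main values were the numbers of listed genes in each direction. For genes with counts, edgeR 4.0.16 (R 4.3.3) was run within each cell type with its quasi-likelihood test, the recovered library sizes and no filter, and p-values were adjusted by Benjamini-Hochberg over the listed higher genes. Standard errors of edgeR folds are its log2 fold change, shrunken by a small prior count, over the square root of F. The folds printed beside them are not shrunken, so the standard errors may be too small for genes with few reads. TMM scaling had been planned; it was run as an alternative only, because every gene with counts had been listed as higher and TMM then centres that change away: with it, 104 B-1a genes passed as higher and 90 as lower, and 62 and 56 follicular B genes. This change of the main scaling was made after seeing the data. Under TMM or DESeq2's own size factors, listed genes changed by less than the median listed gene turn by construction, so such a turn is reported as a property of the scaling and says nothing against a gene's direction. Likewise, a direction kept under them shows only a change above about that of the median listed gene. Genes with 0 reads in both control libraries were given a lower bound of the fold, against 3 reads in each control library; such bounds cover counting error only. The difference of the effect between cell types was fitted with limma 3.58.1 on log2(FPKM + 1) over the 28 genes with library values in both tables, and, as an added alternative, with edgeR on the counts; fold changes on the log2(FPKM + 1) scale understate the change of low genes. With 2 libraries against 2, an exact permutation test of a single gene cannot go below a two-sided p of 1/3, so no such test was used.

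A count test on genes that had been selected on the same libraries is not independent evidence. In simulated tables of 12000 unchanged genes with the real library sizes and dispersions of 0.01 and 0.03, selected by the same fold and p limits with an unmoderated least-squares test, 265 to 458 (B-1a) and 274 to 476 (follicular B) genes were selected, and 94.0% to 95.9% and 90.2% to 93.4% of the higher ones then passed edgeR. In counts simulated without selection, edgeR recovered 92.7%, 96.4% and 100% of genes changed 1.5-, 2- and 4-fold among 325 B-1a genes. It called 0.613% of the unchanged ones. Among 180 follicular B genes it recovered 96.4%, 97.1% and 100% and called 2.22%. These counts were drawn at the common dispersion fitted to the listed genes, 0.00326 in B-1a cells and 0.00134 in follicular B cells. Both are below the 0.01 and 0.03 used above, so the rates hold for that low spread only.

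Before the data were examined, 26 gene lists were fixed (22 of symbols, 4 by symbol pattern), along with the comparisons, the rule for named genes and most alternatives. For each list with at least 5 members in a table, the share listed as higher was compared with the share of that whole table (45.6% in B-1a cells, 50.3% in follicular B cells) by an exact two-sided binomial test, adjusted over the 8 tests. On tables with directions shuffled gene by gene, 1 of 100 shuffles gave a list past this test, and 2 of 2 planted lists passed. Such shuffles break any shared movement of list members, so this rate does not cover lists whose genes move together. Genes in both tables were matched by symbol and their directions compared with Fisher's exact test. The binomial and Fisher tests treat genes as independent draws and do not measure the spread between libraries. Genes that move together can make their p-values too small. Named genes were Cic; in each cell type the 10 largest increases and 10 largest decreases by the authors' fold, with Cic-deficient values all above or below the controls and a mean of at least 1 FPKM in a group; up to 4 members of each list; and up to 15 of the genes in both tables with the largest smaller change. For lower genes the last conditions on values could not be checked. Further members of the fixed lists, the other genes past the test of the difference between cell types and the gene families of the closing section were named after their values were seen. Symbols such as Gm or Rik models, variable segments and pseudogenes were counted but not named (41 and 21 genes). Alternatives were pseudocounts of 0.1 and 5, filters on low values, a replicate block, leaving out each library, other priors, DESeq2 1.42.0, stricter fold and p limits and matching by identifier; others were added after seeing the data. Lists and overlaps were computed with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Near-identical paralogs (such as Hspa1a and Hspa1b, Dynlt1f and its relatives, and the serpin family), overlapping genes (Setdb2 and its readthrough gene) and microRNAs within host genes may share reads and are uncertain.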

Results

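The libraries came from B-1a cells, a self-renewing, innate-like B cell subset that makes natural antibody, and from follicular B cells, the recirculating majority of mature splenic B cells. Cic encodes capicua, a transcriptional repressor that is relieved by receptor tyrosine kinase and ERK signalling, and Cd19-Cre deletes it in the B lineage. The question was which transcripts differ between control and Cic-deficient cells of each subset. There were 2 libraries in each of the 4 groups, with an estimated 40.8 to 53.4 M reads per library. Replicates of every group differed by more than sampling noise, so no library was a second copy of another. The chi-square per gene, over genes with at least 100 reads, was 43.1 between the Cic-deficient B-1a libraries, far above the 5.05 to 5.70 of the other 3 groups. This value grows with the number of reads. The median absolute log2 ratio between replicates was 0.0996 in that group against 0.0667 to 0.0804 in the others, so the typical gene differed only somewhat more. Cic was not among the listed genes of either cell type, so its level in each library was not analysed here and the genotype labels were not checked by it.

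In B-1a cells, known targets of CIC repression were among the 10 named genes with the largest increases by the fold of the authors' deposited table, which rests on FPKM + 1 and understates low genes. Etv5, an ETS transcription factor gene (chromosome 16, 22381313 to 22439570 in GRCm38), went from 2.32 ± 0.221 FPKM in controls to 153.5 ± 25.6 FPKM in Cic-deficient cells (SD, n = 2 each), a log2 fold change of 6.05 ± 0.16 (SE, edgeR adjusted p = 5.59e-06). Etv4, a second gene of that family, had 0 reads in both controls and 644 and 495 reads in the Cic-deficient libraries, at least 208-fold higher. Spred1 and Spred2, which encode inhibitors of RAS-ERK signalling, were 16.6-fold (log2 4.05 ± 0.18) and 11.6-fold (log2 3.54 ± 0.10) higher, and Dusp6, an ERK phosphatase gene, was 4.34-fold higher (log2 2.12 ± 0.09). The other genes of these 10, with their folds by counts, were the serpin gene Serpinb6b (10.6-fold), the diacylglycerol kinase gene Dgkg (18.8-fold from 70 and 39 control reads), the calcium/calmodulin kinase kinase gene Camkk1 (7.49-fold), Trim40 (4.86-fold) and Cyp11a1, which encodes the side-chain cleavage enzyme of steroid synthesis (4.16-fold). Each of these genes had an edgeR adjusted p of 7.57e-05 or lower.

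The list of CIC targets and RTK/ERK feedback genes had 9 of its 20 members in the authors' deposited table for B-1a cells, 8 higher and 1 lower, a larger share of higher genes than the 45.6% of the whole table (exact binomial p = 0.0142, adjusted p = 0.0379). The higher members were Etv5, Etv4, Spred1, Spred2, Dusp6, the clock gene Per2, Dusp4 and the phosphatase gene Ptpn9. All 8 passed edgeR over the listed genes and when adjusted over the list alone. Of all listed higher genes 319 of 325 passed, so passing does not set the list apart. The direction of the 8 held with the scalings of TMM and DESeq2. That shows only that each rose by more than about the median listed gene. Dusp5, another ERK phosphatase gene, was 2.91-fold lower in the authors' deposited table. The other 11 members were not listed.

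**Figure D1:**
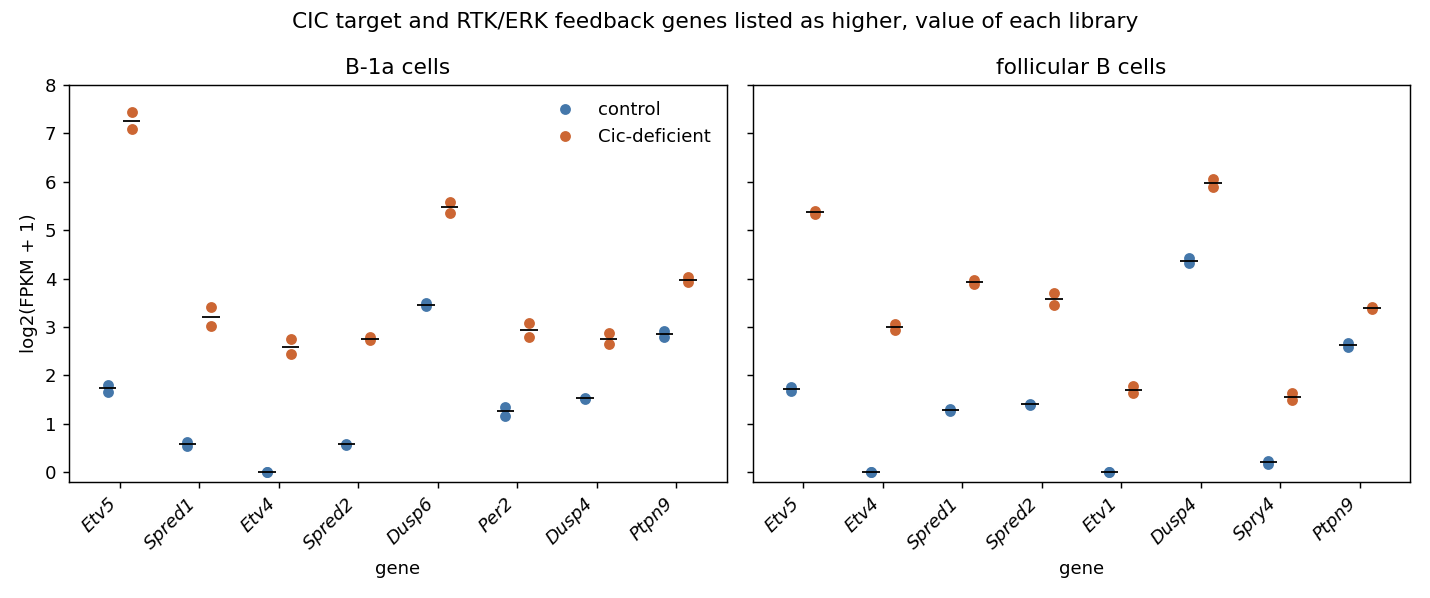
Each point is 1 library and each black line the mean of 2, on a log2(FPKM + 1) axis, for the CIC target and RTK/ERK feedback genes listed as higher in B-1a cells (left) and follicular B cells (right). All 8 genes in each panel have both Cic-deficient libraries above both controls, a condition set by the selection of listed genes, and Etv5 shows the widest gap in both.

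All 6 listed members of the cell cycle list were higher in Cic-deficient B-1a cells (exact binomial p = 0.00905, adjusted p = 0.0362). That test treats the 6 genes as independent, and its p-value is too small if they move together between libraries. They were the mitotic kinase genes Plk1 (2.66-fold, log2 1.41 ± 0.19) and Aurkb, the cyclin B genes Ccnb2 (2.28-fold) and Ccnb1 (2.18-fold), the survivin gene Birc5 (2.21-fold) and the proliferation marker Mki67. All 6 passed edgeR over the listed genes, as did 319 of all 325 listed higher genes, and adjusted over the list alone. With TMM or DESeq2 scaling, which centre on the listed higher genes, Aurkb turned and 5 passed. The other 20 members, among them Top2a, Cdk1 and the Mcm genes, were not listed. Of survival genes, Bcl2l1 was 1.82-fold higher and Bcl2 1.24-fold higher by counts, though with either of those scalings Bcl2 turned and Bcl2l1 no longer passed, and Pmaip1, which encodes the pro-apoptotic NOXA, was 3.15-fold lower in the authors' deposited table. For Bcl2 the fold of the authors' deposited table was larger, 1.48-fold, so counts and FPKM differ for this gene. The cyclin gene Ccnd2 was 3.16-fold higher (481.9 ± 96.3 against 152.5 ± 6.22 FPKM, SD, n = 2 each).

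The 10 named genes with the largest decreases in B-1a cells included 5 genes of cytokines, chemokines and their receptors. In the authors' deposited table, the interleukin 12 subunit gene Il12a was 9.08-fold lower, the stress-induced transcription factor gene Atf3 8.93-fold, the chemokine receptor gene Ccr6 7.78-fold and the immunoglobulin joining chain gene Jchain 5.83-fold. The same deposited table of the authors had Il1b 5.31-fold lower, Dynlt1f 5.18-fold, the lysophospholipid receptor gene Gpr34 4.99-fold, the G protein regulator gene Rgs1 4.63-fold, the interleukin 9 receptor gene Il9r 4.11-fold and the chemokine gene Cxcl2 3.76-fold. No library values were used for these genes, so their spread is not known here beyond the raw p-values of the authors' deposited table, which ran from 0.000555 (Il1b) to 0.0317 (Cxcl2).

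Several fixed lists had listed members that were mostly lower in B-1a cells, none past the adjusted test. In the authors' deposited table, 5 of the 21 myeloid and dendritic cell markers were listed and all were lower: Cd14 (2.46-fold), Adgre1 (2.11-fold), Fcgr3 (1.88-fold), Csf1r (1.81-fold) and Itgax (exact binomial p = 0.0673, adjusted p = 0.135). Of the immediate early genes, 6 were lower and Jun was higher in the authors' deposited table (exact binomial p = 0.135, adjusted p = 0.216), with Ier3 2.36-fold, Klf4 2.28-fold and Egr2 1.56-fold lower beside Atf3. Of the circadian clock genes, Per2 (4.80-fold by counts) and Cry1 were higher, and in the authors' deposited table Nfil3 (2.49-fold), Per1 (2.09-fold), Ciart (1.89-fold) and Nr1d2 were lower (exact binomial p = 0.695, adjusted p = 0.695). Cry1 turned with TMM or DESeq2 scaling, as did Jun.

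Lists with fewer than 5 listed members were counted without a test. The authors' deposited table had 3 plasma cell genes lower in B-1a cells, Jchain, Slpi (2.27-fold) and Sdc1 (1.69-fold), and 3 interferon response genes lower, Oasl2 (2.21-fold), Oas1a (2.14-fold) and Ifit3 (2.04-fold). Genes of the B-1a identity list were lower for Itgam (1.61-fold) and Il10 (1.23-fold) in the authors' deposited table, while the subset's defining marker Cd5 was not listed. The follicular B identity genes Cr2 (2.01-fold) and Ccr7 (1.87-fold), the peptide-loading genes H2-DMb2 (1.23-fold) and H2-DMb1 (1.21-fold) and Hspa1a (1.58-fold) were lower in the authors' deposited table, and Ccr6 and Ccr7 were the 2 listed members of the migration list. Of the marginal zone and Notch list, S1pr3, a sphingosine-1-phosphate receptor gene, was 4.11-fold higher (log2 2.04 ± 0.05) and Hes5 1.95-fold higher by counts, while Cd9 (1.68-fold) and Cr2 were lower in the authors' deposited table. B cell receptor genes were represented by the inhibitory receptor gene Fcgr2b (1.35-fold higher by counts) and Cr2, and the NF-kB list by Bcl3 (1.48-fold higher by counts) and Nfkb2 (1.72-fold lower in the authors' deposited table). With TMM or DESeq2 scaling Fcgr2b and Bcl3 turned and Hes5 no longer passed.

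In total, the authors' deposited table for B-1a cells listed 325 genes as higher and 387 as lower. Changes of at least 2-fold made up 41 of the higher and 67 of the lower genes, and 53.1% of all were under 1.5-fold. With edgeR, 319 of the 325 higher genes passed over the listed genes, and 169 passed when adjusted over 26220 RefSeq genes. These calls were made on genes selected on the same libraries and are no independent evidence. Unchanged simulated genes, selected likewise, passed in 94.0% to 95.9% of cases. The authors' raw p-values, ranked among the listed genes alone, give no gene past a Benjamini-Hochberg adjustment over 26220 RefSeq genes (smallest value 0.777). Genes with a small p-value but a fold under the limit are missing from that ranking. The value is therefore an upper bound, and whether a gene would pass a full adjustment cannot be told.

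In follicular B cells, genes of the same list were among the largest increases by the FPKM + 1 fold of the authors' deposited table; by counts, some genes with few control reads had larger folds. Etv5 went from 2.29 ± 0.112 to 40.3 ± 1.47 FPKM (SD, n = 2 each), a log2 fold change of 4.14 ± 0.06 (SE, edgeR adjusted p = 5.19e-12). Etv4 had 0 reads in both controls and 836 and 760 reads in the Cic-deficient libraries, at least 250-fold higher, and Etv1, another ETS factor gene of this family, had 0 reads in both controls against 402 and 503 reads, at least 136-fold higher. Spred1 was 10.1-fold higher (log2 3.34 ± 0.06), Spred2 6.70-fold (log2 2.75 ± 0.11), the feedback inhibitor gene Spry4 12.5-fold (log2 3.64 ± 0.16) and Dusp4 3.14-fold (log2 1.65 ± 0.07). Outside this list, Ccnd2 was 5.10-fold higher, the claudin gene Cldn10 4.46-fold, Serpinb6b 3.99-fold and the calcium-binding protein gene S100a6 3.20-fold. Each of these genes had an edgeR adjusted p of 3.08e-07 or lower.

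All 8 listed members of the CIC target and RTK/ERK feedback list were higher in follicular B cells, against 50.3% of the whole authors' deposited table (exact binomial p = 0.00782, adjusted p = 0.0362). The 8 passed edgeR over the listed genes and when adjusted over the list alone. Of all listed higher genes 175 of 180 passed, so passing does not set the list apart. The 8 kept their direction with TMM and DESeq2 scaling, so each rose by more than about the median listed gene. The other 12 members, among them Dusp6 and Per2, were not listed. No member of the cell cycle or myeloid marker lists was listed in follicular B cells.

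The largest decreases in the authors' deposited table for follicular B cells were in Kctd12 (10.5-fold), which encodes a GABA-B receptor subunit, Il9r (6.01-fold) and the heat shock protein genes Hspa1b (3.88-fold) and Hspa1a (3.69-fold), a near-identical pair whose reads may be shared. Next in the authors' deposited table came the transcription factor gene Cebpb (3.35-fold), Dmwd (3.16-fold), Tnfaip8 (2.60-fold), Plbd1 (2.58-fold), the lymphotoxin gene Lta (2.49-fold) and Pxdc1 (2.39-fold). Together with Hsph1 (1.27-fold), all 3 listed members of the heat shock list were lower in the authors' deposited table.

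All 4 listed genes of the B-1a identity list were higher in Cic-deficient follicular B cells. The other 9 members, among them Cd5, were not listed, and with fewer than 5 listed members the list was not tested. Bhlhe41, a transcription factor gene needed for B-1a cells, was 2.75-fold higher (10.6 ± 0.255 against 3.85 ± 0.25 FPKM, SD, n = 2 each), Ctla4 3.20-fold, Il10 4.84-fold and Itgam 2.45-fold, the last 3 from control means of 0.238 to 0.339 FPKM. All 4 passed edgeR over the listed genes, as did 175 of all 180 listed higher genes, and adjusted over the list alone. The 4 kept their direction with TMM and DESeq2 scaling, though 3 passed with the latter. That shows only a rise above about that of the median listed gene. Of the follicular B identity list, Cr2 (1.75-fold), Cxcr5 (1.26-fold), Bcl6 (1.24-fold) and Sell (1.24-fold) were lower and Ccr7 was higher in the authors' deposited table (exact binomial p = 0.216, adjusted p = 0.288). Of the migration list, 4 members were lower in the authors' deposited table, led by S1pr2 (2.30-fold) and Ccr6 (2.06-fold), and 2 were higher, Ccr7 and Cxcr4 (exact binomial p = 0.451, adjusted p = 0.515). Cxcr4 was 1.62-fold higher by counts (409.7 ± 15.6 against 253.1 ± 6.47 FPKM, SD, n = 2 each), a call that ended with TMM and DESeq2 scaling.

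Smaller lists in follicular B cells had members in both directions. The plasma cell gene Jchain was 1.69-fold higher and the clock gene Ciart 1.32-fold higher by counts. S1pr3 (2.31-fold) and the Notch target Dtx1 (1.39-fold) were higher by counts, and Notch1 (1.51-fold) and Cr2 were lower in the authors' deposited table. Of B cell receptor genes, Ptpn22 (1.49-fold) and Fcgr2b (1.27-fold) were higher by counts. Immediate early genes were represented by Jund (1.35-fold higher), Fos (1.29-fold higher) and, in the authors' deposited table, Egr2 (1.68-fold lower). In the authors' deposited table, the NF-kB genes Tnfaip3 (1.91-fold) and Nfkb2 (1.43-fold), the survival gene Bcl2a1b (1.22-fold), the Toll-like receptor homolog gene Cd180 (1.21-fold), the T cell marker Lck (1.24-fold) and the NK cell marker Prf1 (1.59-fold) were lower. Of 3 listed histone genes, all higher, Hist1h2bc (1.49-fold) and Hist3h2a (1.32-fold) passed edgeR. Under TMM or DESeq2 scaling, Ciart, Dtx1, Ptpn22, Fcgr2b, Jund, Fos, Ccr7, Hist1h2bc and Hist3h2a turned, and Jchain no longer passed.

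In total, the authors' deposited table for follicular B cells listed 180 genes as higher and 178 as lower, with 16 and 18 at 2-fold or more and 65.9% of all under 1.5-fold. With edgeR, 175 of the 180 higher genes passed over the listed genes and 147 when adjusted over 26220 RefSeq genes. The same limit holds as in B-1a cells, since unchanged simulated genes, selected likewise, passed in 90.2% to 93.4% of cases. No raw p-value in the authors' deposited table passes an adjustment over 26220 genes when ranked among the listed genes alone. As in B-1a cells, that ranking lacks unlisted genes, so whether a gene would pass a full adjustment cannot be told. In both cell types, no member of the erythroid, stromal, sex-linked, immunoglobulin, mitochondrial or ribosomal protein lists was listed.

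**Figure D2:**
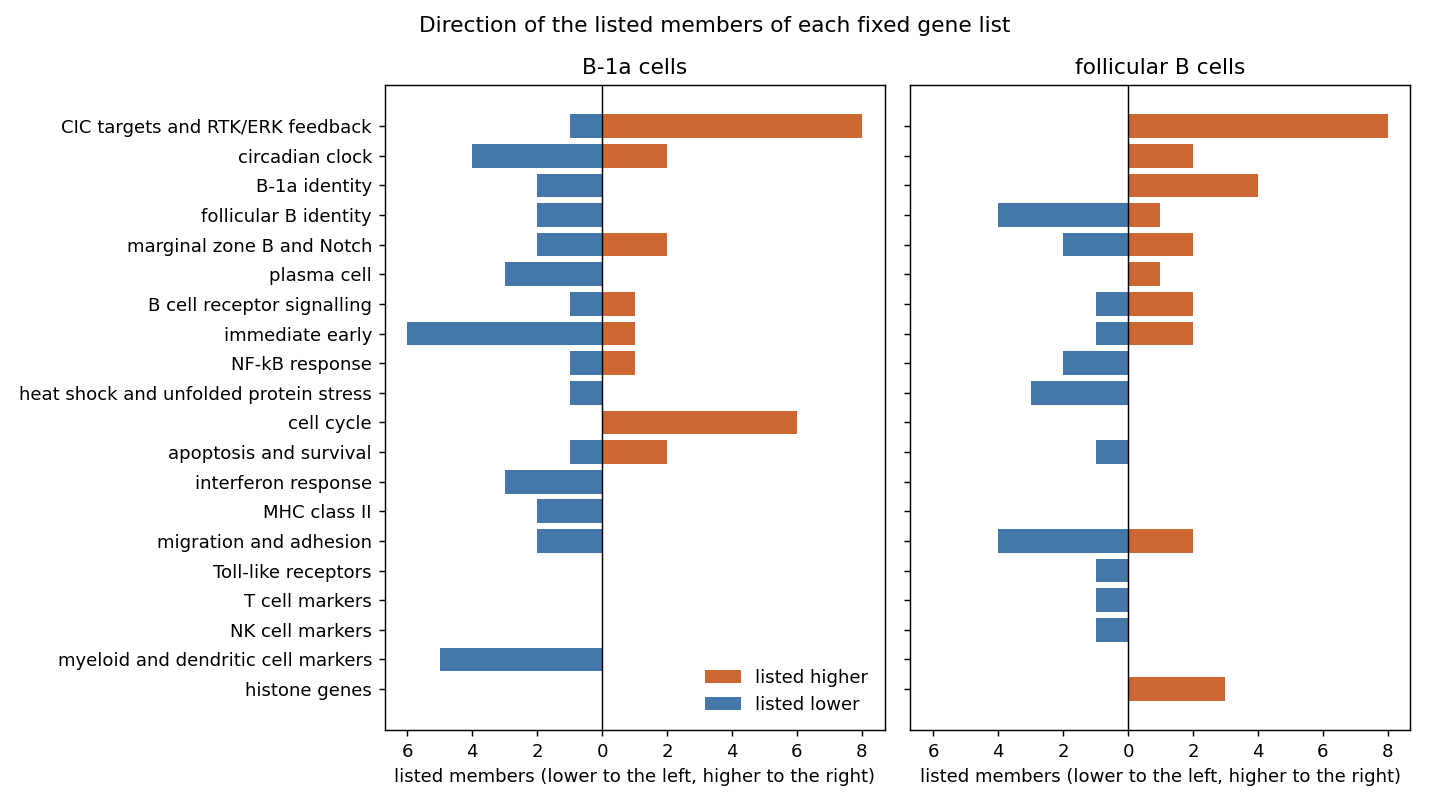
Bars give the number of members of each fixed gene list that the authors' deposited tables list as lower (left of 0) or higher (right of 0) in Cic-deficient B-1a cells (left panel) and follicular B cells (right panel). The CIC target and RTK/ERK feedback list has 8 higher members in each, and the cell cycle list has 6 higher members in B-1a cells, of which Aurkb turned with TMM or DESeq2 scaling, and no listed member in follicular B cells.

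The authors' deposited tables shared 78 genes, 21.8% of the follicular B list. Of these, 28 were higher in both cell types, 37 lower in both and 13 opposite, so 83.3% had the same direction (Fisher's exact test, two-sided p = 7.37e-10). The increases common to both were led by Etv5, Spred1, Etv4, Spred2, Ccnd2, Serpinb6b, Dusp4, S1pr3, the small MAF factor gene Maff and Hspa12a, all of which stayed higher in both with TMM and DESeq2 scaling, while 5 of the 28 turned in B-1a cells and 9 in follicular B cells. Staying higher or turning under these scalings reflects only the size of a change beside that of the median listed gene. The common decreases were led by Il9r (4.11- and 6.01-fold), Plbd1 (2.75- and 2.58-fold), Ccr6 (7.78- and 2.06-fold) and Pxdc1 (1.81- and 2.39-fold), with the B-1a value of the authors' deposited tables first. Cldn10 was 2.14-fold lower in B-1a cells and 3.87-fold higher in follicular B cells in the authors' deposited tables. Among the other opposite genes of the authors' deposited tables were Jchain (5.83-fold lower in B-1a cells, 1.66-fold higher in follicular B cells) and Il10 (1.23-fold lower and 1.79-fold higher); the difference between cell types was not tested for these, which lack library values in B-1a cells. The number of genes the authors tested is not given in the sources used here: 78 shared genes would be the chance number with 3268 tested genes, and 9.72 would be expected with 26220.

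**Figure D3:**
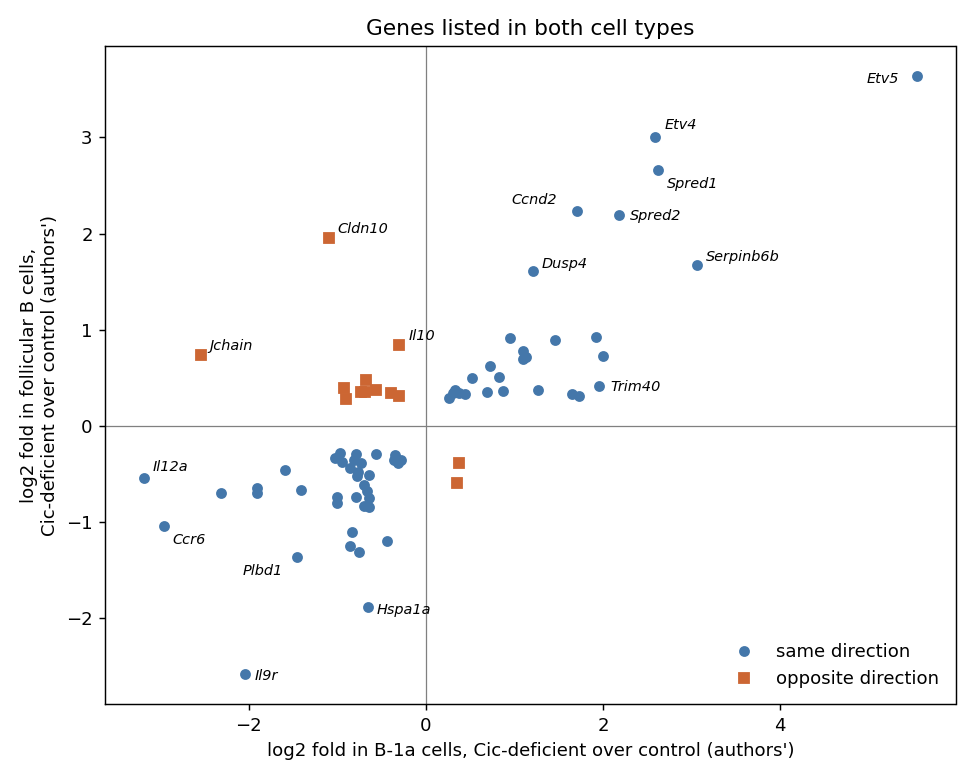
Each point is 1 of the 78 genes in both of the authors' deposited tables, with the log2 fold change of Cic-deficient over control B-1a cells on the x axis and that of follicular B cells on the y axis. The 65 circles have the same direction in both, with Etv5 farthest out, and the 13 squares have opposite directions, with Cldn10 the highest of them.

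The effect of Cic deletion was set against cell type for the 28 genes that were higher in both and so had library values in all 8 libraries. These genes had been listed by a p limit on the same libraries, which favours a small spread. The SEs and p-values below may therefore be too small. With limma on log2(FPKM + 1), 18 genes differed, 15 with the larger increase in B-1a cells and 3 with the larger increase in follicular B cells. Etv4, 1 of the 3, had no reads in any control library. Its value thus compares only Cic-deficient levels between cell types and kits, and is not read as a difference of effect. On the counts, 10 of the 18 passed with the same sign and 4 turned. Etv5 rose more in B-1a cells, by 1.88 ± 0.15 on the log2 scale (SE, limma adjusted p = 2.16e-05), and on the counts its fold was 3.77 times that in follicular B cells. The increase was also larger in B-1a cells on both scales for Pars2 (1.44 ± 0.12), Serpinb6b (1.42 ± 0.12), the TEC-family kinase gene Txk (1.30 ± 0.15), S1pr3 (1.02 ± 0.09), Irf2bpl (0.92 ± 0.08), Hdac4 (0.53 ± 0.09), Ptpn9 (0.36 ± 0.09) and Fam132a (0.35 ± 0.08), as differences of log2 fold change with SE. Pars2, Irf2bpl, Hdac4 and Fam132a lie below the median listed change in follicular B cells and so turn there by construction with TMM or DESeq2 scaling. Ccnd2 had the smaller increase in B-1a cells (-0.58 ± 0.17, limma adjusted p = 0.0178). Without control replicate 1 of the follicular B cells the call of Ptpn9 ended (adjusted p = 0.0535), and that of Ccnd2 ended without either B-1a control or without Cic-deficient follicular B replicate 2 (adjusted p between 0.0582 and 0.0879). Spred1 (-0.03 ± 0.16), Spred2 (0.00 ± 0.12) and Maff (0.04 ± 0.12) did not pass on log2(FPKM + 1). On the counts their folds in B-1a cells were 1.64, 1.74 and 1.51 times those in follicular B cells (edgeR adjusted p = 0.0341, 0.0101 and 0.0420). Since kit and cell type are the same split, a difference here is one between cell types as prepared.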

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

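The tests of the difference between cell types on the counts, and all explanations below, were chosen after the result was seen; the limma test was planned. The interaction test was run on genes selected on the same libraries, so its p-values may be too small. It called 18 genes as differing between the cell types in the size of the effect, Etv4 among them on Cic-deficient levels alone. Given as the log2 fold change in B-1a cells minus that in follicular B cells on log2(FPKM + 1), the values were 1.88 for Etv5, 1.55 for Trim40, 1.44 for Pars2, 1.42 for Serpinb6b, 1.30 for Txk, 1.28 for Cyp11a1, 1.02 for S1pr3, 0.92 for Irf2bpl, 0.56 for Hspa12a, 0.53 for Hdac4, 0.42 for Serpine2, 0.40 for Camk2n1, 0.36 for Ptpn9, 0.35 for Fam132a, 0.32 for Cplx2, -0.37 for Dusp4, -0.40 for Etv4 and -0.58 for Ccnd2. Leaving out 1 library ended the call of 7 of them, with adjusted p-values between 0.0535 and 0.123. These were Dusp4 (6 of the 8 libraries, all but Cic-deficient replicate 1 of either cell type), Etv4 (any control, or Cic-deficient follicular B replicate 1), Camk2n1 (B-1a control 1, follicular B control 2 or Cic-deficient follicular B replicate 1) and Hspa12a (B-1a control 2 or Cic-deficient follicular B replicate 1). The others were Ccnd2 (either B-1a control or Cic-deficient follicular B replicate 2), Ptpn9 and Cplx2 (follicular B control 1 for both).

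For part of these genes the scale may set the sign. Adding 1 FPKM compresses the fold of a gene with a low level. On the counts, which need no such addition, the sign turned for 4 of the 18 genes. These were Trim40, Cyp11a1, Serpine2 and Camk2n1, with control means of 0.0111 to 0.0648 FPKM in follicular B cells. The turned difference passed on the counts for Trim40, Cyp11a1 and Serpine2 but not for Camk2n1 (edgeR adjusted p = 0.0924). Serpine2, for example, went from 5 and 7 control reads to 73 and 75 reads in Cic-deficient follicular B cells, 11.8-fold, against 2.33-fold from 954 and 987 reads in B-1a cells. The same explanation is argued against for the 10 genes that passed on both scales with the same sign, Etv5 among them. Of the other 4, Cplx2 and Hspa12a kept their sign on the counts without passing (edgeR adjusted p = 0.0514 for both), Dusp4 was close to 0 (-0.03, edgeR adjusted p = 0.925), and Etv4 had 0 control reads and so no value. With control values of 0 in both cell types, the limma value of Etv4 compares only the levels of Cic-deficient cells. The library kit stays open for all 18, since there was 1 kit per cell type, so kit and cell type cannot be told apart; a difference in biology between the cell types is likewise untested.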

How the results depend on the processing

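The adjustment over all RefSeq genes, filterByExpr, DESeq2 with recovered sizes, limma at a pseudocount of 1 or with a replicate block and the interaction on counts were added after seeing the data, and TMM, planned as the main scaling, was made an alternative then. Calls of higher genes stayed within 1.5 times 319 (B-1a) and 175 (follicular B) with most alternatives, and ranged over 308 to 320 and 170 to 173 when 1 library was left out, with the lone sample assumed to vary like the others. They fell to 78 and 48 with DESeq2's own size factors and to 104 and 62 with TMM, which by construction centre the listed higher genes (median log2 change 0.00 and 0.02 in B-1a cells, 0.05 and 0.03 in follicular B cells, against 0.72 and 0.64), and to 169 in B-1a cells over all RefSeq genes, where more genes are counted. The genes of the top 10 increases that have a fitted fold, 9 in B-1a cells and 8 in follicular B cells, were followed through every alternative. They kept their direction and call in all 272 pairs of gene and alternative. As they were picked for the largest increases, this says little about the stability of other genes. Other named genes were not followed through every refit. The replicate numbers were not stated to pair libraries, and the deviations of same-numbered libraries correlated at 0.27 and -0.34 across genes; with a replicate block edgeR called 318 and 174, limma 325 and 180, and the interaction test 18.

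Stricter limits left fewer listed genes by construction: at 4-fold, 7 higher and 10 lower in B-1a cells and 5 and 2 in follicular B cells, and at a raw p under 0.01 in the authors' deposited tables, 60 and 108, and 45 and 51. At 4-fold in both, 5 genes were shared, all 5 in the same direction; matching by identifier gave 65 of 78. Requiring no overlap of values and leaving out each library could turn no direction, since all listed higher genes meet that rule and lower genes have no library values, so their 65 shared genes and 3 lists show no stability. Of the 3 list tests that passed, 1 passed at 4-fold, where the other lists had too few members. The interaction test called 14 to 19 genes without 1 library, 13 and 21 with pseudocounts of 0.1 and 5, and 16 on the counts. It reversed on the counts for Trim40 (-2.37), Serpine2 (-2.34), Cyp11a1 (-1.39), Camk2n1 (-1.08) and Spred1 (0.71), at 0.1 for Serpine2 (-1.24), Cyp11a1 (-0.41) and Camk2n1 (-0.29), and at 5 for Spred2 (-0.29) and Maff (-0.25); for all of these the added constant is large beside a level in 1 cell type. Leaving out libraries and adding a pseudocount gave no value for Cic, since Cic was not listed. Depth limits the genes with under 100 reads per control library, such as Dgkg and Spred2 in B-1a cells and Trim40 in follicular B cells, and genes listed as lower have no counts to judge by.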

Other observations

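The gene families, the tests of shared genes by fold, of raw p-values and near Cic were chosen after the values were seen, and so was the use of the planned binomial tests of fixed lists as tests of explanations. Beyond the fixed cell cycle list, 17 of 18 listed genes of the kinetochore, the spindle and mitotic exit were higher in Cic-deficient B-1a cells, up to 2.05-fold in the authors' deposited table. They included the centromere protein genes Cenpa, Cenph, Cenpm and Cenpn, the NDC80 complex genes Spc24, Spc25 and Nuf2, and Tpx2, Nusap1 and Kif22, while Racgap1, needed for cytokinesis, was lower. All 17 passed edgeR with the recovered library sizes, as did 319 of all 325 listed higher genes. With TMM and DESeq2 scaling, which subtract about the median listed change by construction, 7 and 2 passed as higher and 2 and 1 as lower, and Cenpa, Cenph, Cenpn and Kif20b turned in both. All 9 listed replication factor genes, among them Orc1, Gins2, Fen1, Rfc4 and Rfc5, were 1.31- to 1.49-fold higher in the authors' deposited table; by the same construction 8 of the 9, all but Orc1, turned with either scaling. In follicular B cells the listed genes of these groups were Kif4, Cep55 and Dna2, each lower, by 1.25- to 1.30-fold in the authors' deposited table.

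All 6 listed chemokine ligand genes (Cxcl2, Cxcl1, Ccl3, Cx3cl1, Ccl7, Ccl24) and all 6 listed genes of interleukin ligands with a numbered symbol (Il12a, Il1b, Il1a, Il6, Il15, Il10) were lower in Cic-deficient B-1a cells in the authors' deposited table, by 1.72- to 3.76-fold and 1.23- to 9.08-fold. Ebi3, which encodes an interleukin 27 subunit and falls outside that symbol pattern, was 1.34-fold higher by counts. In follicular B cells, Il18 (1.98-fold), Il10 (1.79-fold) and Ccl4 (1.22-fold) were higher and Il12a (1.46-fold) lower in the authors' deposited table, where Ccl4 turned with TMM and DESeq2 scaling. Genes of dual-specificity phosphatases went both ways in B-1a cells, with Dusp6 and Dusp4 higher and Dusp5, Dusp14, Dusp2 and Dusp10 lower. Serpin genes did too: Serpinb6b, Serpinb1a, Serpine2 and Serpinc1 were higher, and Serpina3f, Serpina3g and Serpinb2 lower, with Serpinc1 turning under both scalings; members of this family are similar in sequence.

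Some myeloid and inflammatory transcripts were listed as lower in Cic-deficient B-1a cells, though the fixed myeloid list did not pass its test and no list of inflammatory genes had been fixed, and such a pattern would have more than 1 candidate explanation. Fewer carried-over myeloid cells in these sorts would lower the fixed myeloid markers together, and the 5 that were listed were all lower, though not past the planned test (exact binomial p = 0.0673 before adjustment). Other genes with myeloid expression, picked after their values were seen, were higher by counts, among them Clec12a (2.14-fold), Lrrc25 (2.06-fold) and Cd36 (1.84-fold), which goes against a loss of all myeloid transcripts, but B cells can express such genes too. None of 6 abundant markers named for this test (Lyz2, S100a8, S100a9, C1qa, C1qb, C1qc) was listed, so their levels cannot decide it, the sort required CD19, and Fcgr3 and Itgax can also be expressed by B cells. A weaker activation or handling response may lower the immediate early genes, of which 6 of 7 were lower (exact binomial p = 0.135), short of the threshold. These explanations and an effect of Cic loss in B-1a cells themselves cannot be told apart. How the libraries were split over sorts and handling is not given in the sources used here. There were also only 2 libraries a group, and no library values were used for lower genes.

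With an unadjusted p limit, part of the listed genes could be chance. Of the shared genes with at least 1.5-fold in either table, 54 of 63 had the same direction (exact binomial p = 6.11e-09 against 50%). This argues against chance calls for this set if the libraries of the cell types are independent and the genes do not move together. Of the shared genes under 1.5-fold in both, 11 of 15 had the same direction (exact binomial p = 0.118), too few to decide. Whether both cell types came from the same mice is not stated; if so, differences between individual mice could also be shared, which was not tested. For the genes listed in a single table, the sources used here do not give the number tested: 14240 tested genes in B-1a cells and 7160 in follicular B cells would give as many by chance at a raw p of 0.05, before the fold limit. With both limits, the simulated tables of 12000 unchanged genes gave 274 to 476 genes in follicular B cells, a range that holds the 358 listed. In B-1a cells they gave 265 to 458, fewer than the 712 listed. The number of genes and the dispersions were assumed there, so these ranges do not decide it. Of the raw p-values in the authors' deposited tables, 55.3% in B-1a cells and 58.9% in follicular B cells were under 0.025 (exact binomial p = 0.00491 and 0.000845 against 50%), more than an even spread would give, but the fold limit can also shift the p-values of chance calls, so this does not decide it.

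Variants carried along with the floxed Cic allele on chromosome 7 could also separate the genotypes. Of the 65 shared genes with the same direction, 1 lay within 20 Mb of Cic. This argues against variants that act on nearby genes as the whole cause of that pattern. It cannot speak to variants that act on genes elsewhere, which were not tested. Listed protein-coding genes near Cic were set against all protein-coding RefSeq genes other than olfactory and vomeronasal receptor genes, in 3 windows and both cell types, a family of 6 tests. Within 5 Mb there were 13 in B-1a cells against 6.85 expected (Fisher's exact test, two-sided p = 0.0282) and 0 in follicular B cells against 3.39 (p = 0.0533, Fisher's exact test). Within 10 Mb the exact p-values were 0.339 and 0.565, and within 20 Mb 0.579 and 0.344. The smallest of the 6 gave an adjusted p of 0.160, and the genes the authors tested are not known, so an effect of nearby variants on single genes stays open.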
